A study of Caenorhabditis elegans with 4 samples.

How the data were processed

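The samples came from a Caenorhabditis elegans strain whose transgene carries nfya-1 fused to GFP and a FLAG tag, in an unc-119 mutant background rescued by the unc-119 gene of the same construct. NFYA-1 is an A subunit of NF-Y, the trimeric transcription factor that binds CCAAT boxes. Per the labels' protocols, hermaphrodites were grown at 20 °C and collected as young adults. The animals were fixed with 2% formaldehyde, and chromatin bound by the tagged protein was precipitated with an anti-GFP antibody. Part of each lysate was kept as input DNA. The series holds 2 ChIP samples and 2 inputs. The labels give them replicate numbers but do not say whether the replicates were separate cultures, so the agreement between them may in part be technical.

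The authors deposited 3 peak lists, 1 for each ChIP replicate and 1 named as combined. Per the file headers and columns, the peaks were called with PeakSeq on the genome build WormBase WS180, and each peak carries a q-value and no other measurement. How the combined list was made from the replicates, the PeakSeq version, the aligner, the filters and the q limit are not given in the sources used here. The largest q was 6.02e-05 in replicate 1, 7.61e-05 in replicate 2 and 0.000108 in the combined list. The lists thus ended at different values, and whether different limits were applied is unknown. No read counts or coverage were used, so the sequencing depth behind each peak is unknown, and the inputs have no values of their own here. A q-value depends on depth as well as on enrichment. It was used as −log10 q, to describe and rank peaks within a list, to correlate values and ranks at sites called in both replicates, and to compare the lists at the same sites. Since the depth is unknown, a lower q in one list than in another is a difference between q-values and not a measure of stronger binding.

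The replicate 1 file held 1641 lines, of which 618 were distinct. Of the distinct lines, 476 were written 3 times, 71 were written 2 times and 71 once. By how often each line was written, the lines were sorted into 2 versions of a list of 547 sites. One version held the lines written 2 or 3 times, and the other held those written 1 or 3 times. The order of the lines was not used, so neither version need be the output of a single run. The version with the lines written 2 times was used as replicate 1, and the other version was an alternative. The replicate 2 and combined lists had no repeated line and held 695 and 1333 peaks.

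Peaks were called shared when they overlapped by at least 1 bp. The share expected by chance came from 100000 circular shifts of one list within each chromosome, with a one-sided permutation p of which 1e-05 is the smallest value possible. The last peak end of any list on a chromosome served as its length, both for the shifts and for densities per Mb, since chromosome lengths of WS180 were not used here. Medians of −log10 q were compared by a two-sided permutation test with 100000 resamples, and correlations across pairs of peaks by permuting one member. Pairs were one-to-one, formed by the largest overlap. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks along a chromosome are not independent, and neither are the combined and replicate lists, which come from the same libraries. The number of peaks per chromosome was compared with its share of the spanned length by an exact binomial test and by a two-sided permutation of whole 1 Mb segments between chromosomes, with Benjamini-Hochberg adjustment over the 6 chromosomes. The segment permutation and the tests of chromosomes other than X were added after the data were seen. The test of X had been set to run only with chromosome lengths of the build; running it with the spanned lengths was a departure, also decided after the data were seen. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Tested on simulated lists of the size of the replicate 1 list, the overlap code recovered a planted share of 60.0% as 60.1% and the correlation code a planted Pearson r of 0.7 as 0.702. A planted median difference of 3 between shared and unshared peaks was recovered less closely, as 3.24. The correlation was checked on 329 simulated pairs. Simulated −log10 q followed a normal distribution with no lower limit, and shared sites were slightly moved copies. The real values are skewed and end at a weakest site, so the simulation checks the code and not the tests under that setting.

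The peaks named in the text follow a rule fixed before the data were examined: the 20 combined peaks with the lowest q that overlapped a peak in both replicates. Planned tests of peaks at gene starts, of CCAAT in peak centres and of promoter peaks in 20 gene lists needed a genome and annotation of WS180, and were not run. The gene table used for checking names was of another assembly, WBcel235, and coordinates were not carried between builds. Sites are therefore given by position, and the genes near them were not analysed here. The rule also named nfya-1 and unc-119, both carried by the transgene, and egl-5 and tbx-2, genes that NFYA-1 is known to act on; binding at these genes was not analysed here for the same reason. Sites described by their width, or by their absence from a list, were chosen after their values were seen. Alternatives covered the definition of overlap, the strength limit, list sizes, merging of neighbouring peaks, the version of the replicate 1 list, and the use of 1 replicate list in place of the combined list.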

Results

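Binding of NFYA-1, an A subunit of the CCAAT-binding transcription factor NF-Y, was mapped by ChIP-seq in young adult C. elegans hermaphrodites carrying a GFP-tagged copy of the protein. The series holds 2 ChIP replicates, each with an input. The deposited peak lists, on the genome build WS180, gave 547 sites for replicate 1, 695 sites for replicate 2 and 1333 sites in the list that combines them. Peaks were narrow. The median width was 467 bp in replicate 1, 491 bp in replicate 2 and 485 bp in the combined list, and the combined peaks covered 924 kb in all. The authors' q-values spanned a −log10 q from 3.96 to 241 in the combined list, with a median of 7.10. Read depth is unknown, so the precision of each peak cannot be given beyond its q-value.

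The 20 combined peaks with the lowest q-values all overlapped peaks in both replicates. The strongest combined peak lay on chromosome III at 8416863 to 8418143, with a −log10 q of 241, and it was also the strongest site of replicate 2 at 171. Replicate 1 gave 128 at this site, and its own strongest site lay on chromosome III at 1617940 to 1619611 in the combined list, where replicate 1 reached 136 and replicate 2 reached 139. The next strongest combined sites lay on chromosome II at 5659400 to 5662344 with a −log10 q of 180.5, on X at 6091320 to 6093530 with 174 and on I at 7020782 to 7021948 with 151. Chromosome V carried a site of 3319 bp at 6098572 to 6101890 with a −log10 q of 132, and X a second site at 4523396 to 4524492 with 129.6. On chromosome IV the strongest site lay at 11118527 to 11119627 with 128.9.

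Below these 8 sites, −log10 q fell to 96.2 at a site on chromosome V at 14685520 to 14686530 and to 89.4 at a site on IV at 8431010 to 8433194. The remaining 10 of the 20 strongest sites had values from 86.6 down to 68.1. They lay on X at 7068291, 16929380 and 1503403, on I at 9788368 and 536408, on V at 723716 and 6220724, on III at 4281733 and 9570745, and on II at 12338983, each given by its first base. The 20 sites were spread over all 6 chromosomes, with 5 on X, 4 each on III and V, 3 on I and 2 each on II and IV. Their widths ran from 405 to 9356 bp. Replicate 2 had the lower q-value at all 20, with −log10 q from 16.37 to 171 against 10.4 to 136 in replicate 1, and the combined list had a lower q-value than either replicate at all 20. The genes at these positions were not analysed here.

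The first comparison asked how far both replicates found the same sites. Of the 547 replicate 1 sites, 447 overlapped a replicate 2 site, which is 81.7% (95% interval 78.2 to 84.9%). Of the 695 replicate 2 sites, 444 overlapped a replicate 1 site, which is 63.9% (60.2 to 67.5%). Circular shifts of the lists gave 0.998% and 0.784% on average, and no shift among 100000 reached the observed overlap in either direction (one-sided permutation p = 1e-05, the smallest possible). With 547 top sites taken from each list, the shares were 73.5% and 72.8%. Midpoints of paired sites lay a median of 27.8 bp apart, and 406 of 442 pairs had midpoints within 200 bp.

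Sites found in both replicates were the stronger ones. All of the 100 strongest replicate 1 sites and 99 of the 100 strongest replicate 2 sites were found in the other replicate, and 77 sites of each were among the 100 strongest of both. Among the weakest sites the share fell to 55.4% in replicate 1 (139 sites) and to 33.5% in replicate 2 (176 sites). Shared sites of replicate 1 had a median −log10 q of 7.07 (quartiles 5.45 and 10.4, n = 447 sites), and unshared sites 4.86 (4.53 and 5.52, n = 100 sites). In replicate 2 the medians were 8.25 (6.003 and 13.6, n = 444 sites) and 5.17 (4.58 and 6.21, n = 251 sites). The difference was 2.21 in replicate 1 and 3.08 in replicate 2, and both gave the smallest possible two-sided permutation p of 1e-05. The weakest listed site had a −log10 q of 4.22 in replicate 1 and 4.12 in replicate 2. A site near such a value may miss the other list by noise alone. Some difference in this direction is thus built into the lists, and the p does not separate it from other sources. Shared sites were also wider in replicate 1, with medians of 495 and 403 bp (two-sided permutation p = 0.0273). In replicate 2 the medians of 507 and 480 bp could not be told from chance (permutation p = 0.222). A wider site is more likely to overlap another by at least 1 bp, so some difference in width may be built in as well.

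At the 442 pairs of sites called in both replicates, peak strength was correlated. Pearson's r was 0.928 and Spearman's rho 0.723 across pairs, each with the smallest possible permutation p of 1e-05, and without the 2 pairs farthest from the replicate 1 median r was 0.907. Pairs of sites are not independent replicates. Widths gave an r of 0.809 and a rho of 0.874, with the same permutation p of 1e-05. All 4 correlations had this p, so Benjamini-Hochberg adjustment leaves it unchanged. Replicate 2 had the lower q-value at 296 of the 442 pairs, which is 67.0%, and the median ratio of its −log10 q to that of replicate 1 was 1.14 (quartiles 0.933 and 1.44).

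**Figure D1:**
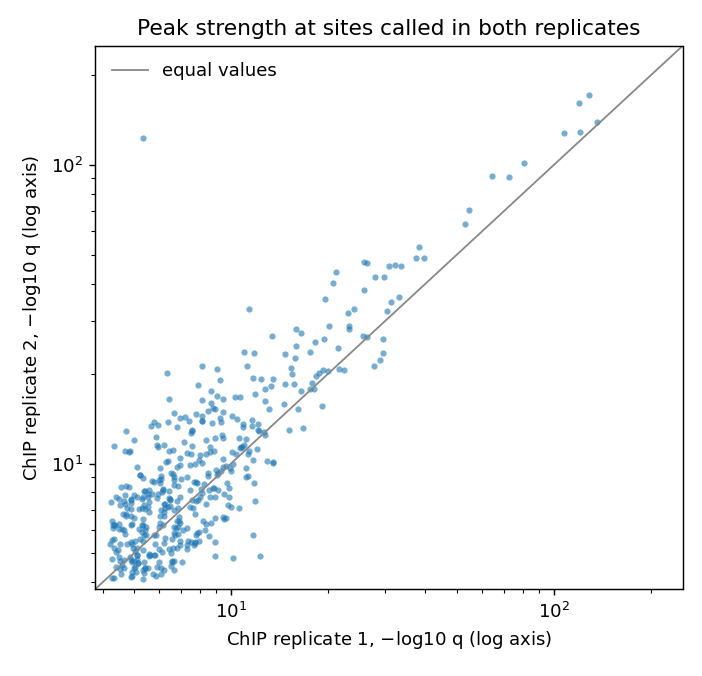
Strength of 442 pairs of overlapping NFYA-1 peaks, with −log10 q of ChIP replicate 1 on the horizontal axis and of ChIP replicate 2 on the vertical axis, both logarithmic; each point is a pair and the line marks equal values. Replicate 2 lies above the line at 296 pairs; the isolated point at upper left is the chromosome V site at 6098572 to 6101890, where replicate 1 called 2 peaks and the weaker one had the larger overlap.

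The combined list was compared with the replicate lists it goes with. It held 546 of the 547 replicate 1 sites and 688 of the 695 replicate 2 sites. Of its 1333 peaks, 435 overlapped a peak in both replicates (32.6%, 95% interval 30.1 to 35.2%), 99 overlapped only replicate 1 (7.43%), 242 overlapped only replicate 2 (18.2%) and 557 overlapped neither (41.8%, 39.1 to 44.5%). Peaks found in both had a median −log10 q of 15.3 and a median width of 587 bp. Peaks found in neither had medians of 5.13 and 422 bp. At 429 of the 435 peaks found in both, the combined q-value was lower than that of either replicate.

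The share of combined peaks recovered in both replicates rose with strength. Of 135 peaks with a −log10 q of 20 or more, 134 were found in both (99.3%) and none in neither. Of 284 peaks between 10 and 20, 228 were found in both (80.3%), and of 267 peaks between 7 and 10, 67 were (25.09%). Below a −log10 q of 5, none of 284 peaks was found in both and 255 were found in neither (89.8%). The one peak of 20 or more not found in both lay on X at 8019397 to 8022157, with a −log10 q of 21.9 in the combined list. Replicate 2 had 2 peaks there, of up to 7.24, and replicate 1 had none. The combined and replicate lists rest on the same libraries, so these shares describe the lists and are not independent evidence for a site.

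**Figure D2:**
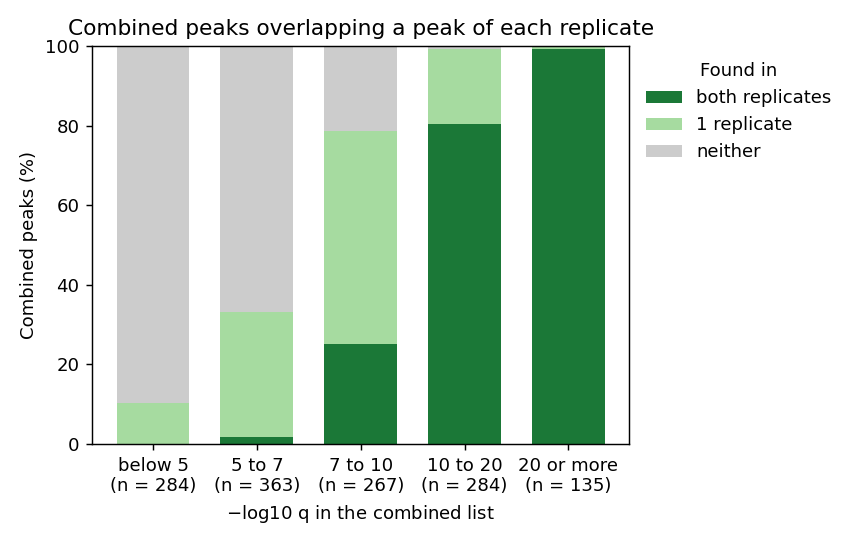
Share of combined NFYA-1 peaks (percent, vertical axis) that overlapped a peak in both replicates, in 1 replicate or in neither, by −log10 q in the combined list (horizontal axis, with the number of peaks in each class). The share found in both goes from none of 284 peaks below 5 to 99.3% of 135 peaks at 20 or more.

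NFYA-1 peaks were densest on chromosome III. It carried 332 of the 1333 combined peaks, or 24.9% (95% interval 22.6 to 27.3%), over 13.8% of the spanned length, which is 24.2 peaks per Mb. The other chromosomes held 9.53 to 14.02 peaks per Mb. Chromosome V had the lowest density, 9.53 peaks per Mb, with 198 peaks or 14.9% over 20.9% of the spanned length. X held 210 peaks, 15.8% (13.8 to 17.8%) over 17.7% of the length.

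Each whole 1 Mb segment of chromosome III held 24.2 ± 10.96 combined peaks (SD, n = 13 segments), against 11.7 ± 4.89 in the rest of the genome (n = 83 segments). The permutation of whole segments gave an adjusted p of 6e-05 for III and 0.0266 for V. This permutation treats the segments of a chromosome as independent units, which was not tested, so its p may be too small. For X it gave 0.567, and the exact binomial test gave p = 0.0621 before and 0.0932 after adjustment, so a lower share on X was not established. Chromosome II had 12.7% of peaks over 15.1% of the length. Its exact binomial test gave an adjusted p of 0.0257, but the permutation of segments gave 0.414. Shares of one total are tied, so the excess on III lowers the shares of the other chromosomes. The tests of X, II and V kept III in the comparison. In peaks per Mb, X at 11.9 and II at 11.2 lay between V at 9.53 and IV at 14.02. The low shares of X and II therefore do not show a deficit apart from the excess on III.

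The excess on III and the low share of V were present in each replicate list. V was compared with all other chromosomes, III included, so its low share partly follows from the excess on III. How large that part is was not tested. V also had the lowest density, 3.23 peaks per Mb in replicate 1 and 3.85 in replicate 2. The next lowest was I, with 4.41 and 5.75. Chromosome III held 26.9% of replicate 1 and 25.9% of replicate 2 sites, with an adjusted segment permutation p of 6e-05 in both. Chromosome V held 12.2% and 11.5%, with adjusted p-values of the same permutation of 0.0175 and 0.00231. Among combined peaks found in both replicates, 27.4% lay on III (23.2 to 31.8%), and among those found in neither 23.2% did, a difference that did not pass a two-sided Fisher's exact test (p = 0.140). The comparison of III and V was chosen after the counts were seen.

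**Figure D3:**
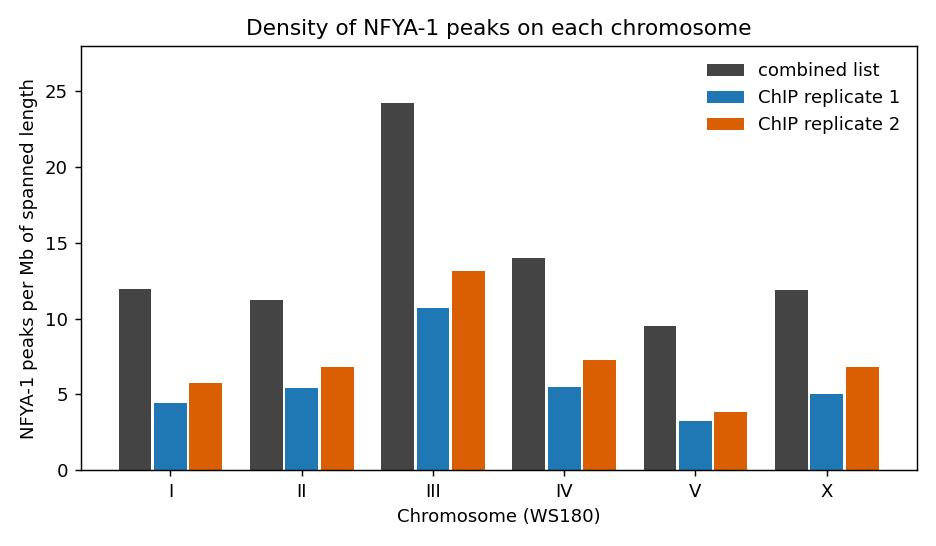
NFYA-1 peaks per Mb of spanned length (vertical axis, from 0) on each chromosome (horizontal axis) in the combined list and in each ChIP replicate; bars are single values with no error bar. Chromosome III is highest in all 3 lists, at 24.2 peaks per Mb in the combined list, and V lowest, at 9.53.

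A minority of NFYA-1 sites were broad. Of the combined peaks, 195 were wider than 1000 bp (14.6%), 18 were wider than 3000 bp and 6 were wider than 5000 bp, and all of these 6 overlapped peaks in both replicates. The widest lay on chromosome II at 10541839 to 10556243. It spanned 14405 bp with a −log10 q of 61.0, and it appeared as 3 peaks in replicate 1 and as 1 peak of 11079 bp in replicate 2. The second widest, of 9356 bp, lay on V at 6220724 to 6230079 and was split into 3 peaks in each replicate. Width and −log10 q were correlated across the 1333 combined peaks, with a Pearson's r of 0.325 and a Spearman's rho of 0.306 (permutation p = 1e-05 for each, the smallest possible). Both values come from the same peak calling, which may itself link them, so this correlation describes the list only.

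The lines of the deposited replicate 1 list could be sorted into 2 versions of its 547 sites. Ends and q-value were identical at 476 sites, and 70 sites differed in their ends. The largest shift of an end was 499 bp and the median change in width 3.42%, and the q-value was unchanged at 43 of these 70 sites. One site in each version had no counterpart in the other. The sites that differed lay in 15 of the 99 segments with a site on a grid at multiples of 1 Mb, partial segments at chromosome ends included, and no segment held both kinds. With the other version in place of the one used, the share of replicate 1 sites found in replicate 2 was 81.5%.

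**Figure D4:**
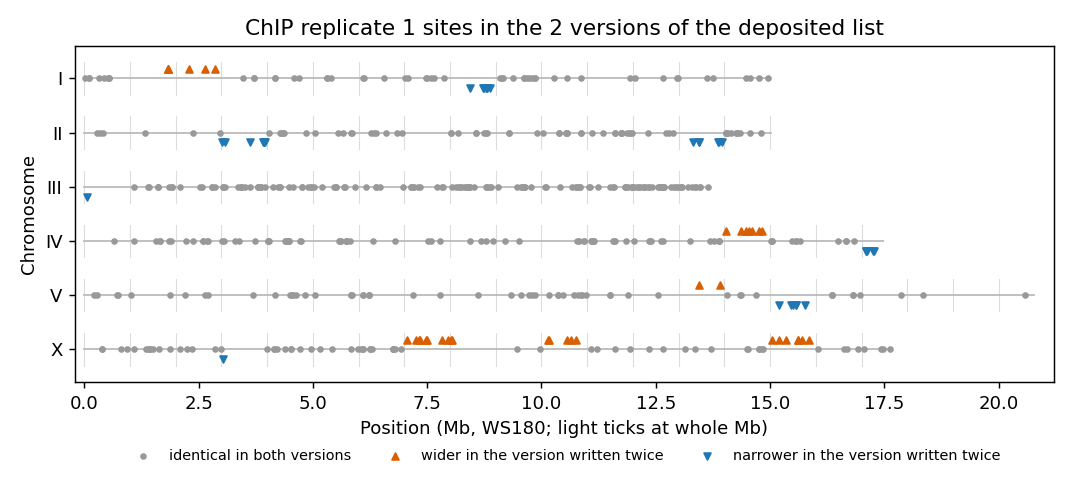
Position of ChIP replicate 1 sites (horizontal axis, Mb, with light ticks at whole Mb) on each chromosome (vertical axis); grey points are 476 sites identical in both versions of the list, and triangles are 70 sites that were wider (up, 37 sites) or narrower (down, 33 sites) in the version used as replicate 1. Sites with no counterpart are left out; triangles and grey points do not share a segment between ticks.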

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

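Across 8 results, 46 alternatives were computed, and 42 kept the direction and the side of the threshold, or stayed within the 95% interval where there was no test. The share of replicate 1 sites found in replicate 2 ran from 73.5% to 81.8%, and the reverse share from 58.4% to 72.8%. For these overlaps the side of the threshold could hardly change, since circular shifts of the main lists gave 0.998% and 0.784% on average. Both ranges reach outside the 95% intervals of the main shares, 78.2 to 84.9% and 60.2 to 67.5%. Spearman's rho of shared sites ran from 0.719 to 0.746, the highest with a reciprocal overlap of 50%. Pairs formed by the lowest q in place of the largest overlap raised Pearson's r from 0.928 to 0.971. The share of combined peaks found in both replicates moved from 32.6% to 29.6% with a reciprocal overlap of 50%, to 28.7% with midpoints within 200 bp and to 29.3% with equal numbers of top peaks; the stricter construction of these settings lowers the count. In replicate 2, the comparison of shared with unshared sites by width in place of q gave a difference of 27 bp that no longer passed the threshold (permutation p = 0.222). The share on X passed the threshold under none of its alternatives and ran from 15.8% to 17.3%, with 16.3% to 17.3% in the lists of single replicates. The share on III stayed between 21.98% without its densest segment and 27.4%, and ran from 25.9% to 26.9% in the lists of single replicates. The alternatives on the version and repeated lines of the replicate 1 list, the common q limit, pairs by lowest q, whole segments and chromosome III were added after the data were seen. Enrichment beside the q-value is not in these lists, so it was not tried as another score, and the tests that needed a WS180 genome or annotation were not run under any setting. No paired analysis was possible because the inputs, which share replicate numbers with the ChIP samples, have no values here. With the depth unknown, a site missing from a replicate list was not detected at that list's limit, which does not show that it was unbound.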

Other observations

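All tests in this part were chosen after the data were seen. NFYA-1 peaks tended to lie near other peaks. In the combined list, 264 peaks had the next peak less than 5 kb away. The strongest combined peak that neither replicate list held lay on chromosome V at 6275987 to 6278734, with a −log10 q of 12.9 over 2748 bp. Conversely, 1 replicate 1 site and 7 replicate 2 sites were not in the combined list, and none of these 8 was in the other replicate. The one with the lowest q lay on chromosome I at 382372 to 382862 and had a −log10 q of 5.91 in replicate 2.

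The spacing was tested against 1000 random placements of the same peaks within their own 1 Mb segments, which gave 82 to 148 close neighbours. The observed 264 lay above all of them, so chance at the density of each segment is argued against. Broad sites split by the peak caller into several peaks would also give close neighbours. After peaks less than 1 kb apart were merged, 180 close neighbours remained, against 72 to 132 in random placements, so splitting over such distances does not account for all of them. The replicate lists treated in the same way gave 50 against 7 to 35 in replicate 1 and 64 against 17 to 48 in replicate 2. In these comparisons of merged lists, the random placements were not merged. They therefore also counted overlaps and gaps under 1 kb, which a merged list cannot hold, so the 2 counts are not of quite the same thing. The extra gaps raise the counts of the placements. A hypothesis that stays open is that NFYA-1 sites follow gene-dense stretches shorter than 1 Mb, which may be tested with a WS180 annotation; sites split over more than 1 kb also stay open.

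Chromosome III held 24.9% of combined peaks over 13.8% of the spanned length. One dense segment does not account for it: the segment from 12 Mb held 50 combined peaks, and without it III still held 22.1 ± 8.11 peaks per segment (SD, n = 12 segments) against 11.7 elsewhere (two-sided permutation p = 1e-05, the smallest possible). On III, 12 of 13 segments lay above the mean of the others. Peaks that only weak evidence supports are argued against as the whole source, since 27.4% of peaks found in both replicates lay on III. The share was lowest among the strongest combined peaks. Of 135 peaks with a −log10 q of 20 or more, 28 lay on III (20.7%, 95% interval 14.2 to 28.6%). The weaker classes gave 22.3% to 29.2%. Higher read depth or copy number of III in these libraries was not tested, since coverage was not used here, and neither was gene content, so a preference of NFYA-1 for chromosome III remains a hypothesis that may or may not survive those checks.

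The 2 versions of the replicate 1 list follow a grid. On a grid at multiples of 1 Mb, partial segments at chromosome ends included, 0 of 99 segments with a site mixed sites that differed between versions with sites that did not. Permuting the labels among sites gave 36 to 56 mixed segments in 1000 draws, and moving the grid by 100 to 900 kb gave 7 to 21. Within each of the 13 segments with 2 or more differing sites, all of these sites changed width in one direction, but the direction differed between segments: of the 15 segments that differed, 8 had wider and 7 narrower sites in the version used as replicate 1. A separate threshold per 1 Mb segment in repeated runs of the peak caller, which may have been set by chance in each run, would give this pattern. The versions were sorted by how often a line was written, so the number of runs cannot be told. Different reads in the 2 versions are argued against by 87.0% of sites being identical in ends and q. In the 15 segments that differed, both versions listed 71 sites and shared 70, so peak edges moved more often than calls. No biological explanation was tested, since both versions describe one sample.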
